A study of Mus musculus and Homo sapiens with 29 samples.

How the data were processed

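The series held 29 samples in 14 groups: 12 RNA-seq libraries and as many ATAC-seq libraries of mouse cells, 3 CUT&RUN libraries of human erythroblasts grown from CD34-positive cells for 7 days, and 2 CUX1 ChIP-seq libraries of the K562 line. Groups were taken from the sample titles, which give the assay, the cell type (MEP or RII), the genotype (Renilla, Cux1mid or Cux1low) and a replicate number, and from the source name for CUT&RUN. Per the submitters' processing notes, STAR, DESeq2, BWA, MACS2 and DiffBind were used with the builds mm10 and hg19. Which tool made which file, their versions, the strand setting of the counting and the trimming, duplicate and Tn5 shift steps of ATAC-seq are not given in the sources used here. The comparisons, main tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined.

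Expression values were deposited by the authors as CPM, read counts scaled to the same total in each library, in a table per cell type. Every value was a whole multiple of the smallest step of its column (100% of values within a tolerance of 0.01 reads), so whole reads were recovered. The recovered totals were 24703855 and 18682301 reads for MEP Renilla, 22837294 and 21281211 for MEP Cux1mid, 21344143 and 21524364 for MEP Cux1low, 10154001 and 11518989 for RII Renilla, 10743801 and 9860840 for RII Cux1mid, and 11942669 and 12596085 for RII Cux1low. A count of 0 allows up to 3 reads, which is 0.121 to 0.161 CPM in MEP and 0.238 to 0.304 CPM in RII, and covers counting error only. The 22505 entries included 27 whose gene names had been turned into dates by a spreadsheet. These took 0.283 to 0.302% of reads in MEP and 0.47 to 0.629% in RII and were not named. Of all entries, 21548 (95.7%) matched a symbol of the RefSeq table of mm10 and 22358 a symbol or synonym, from which mouse gene coordinates were taken.

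Genes with at least 1 CPM in at least 2 of the 6 libraries of a cell type were tested, 10746 in MEP and 11166 in RII. Values were transformed to log2(CPM + 1), so fold changes of low genes are understated, and limma 3.58.1 in R 4.3.3 was fitted to the 3 genotypes of each cell type with a trended prior variance. Its moderated two-sided tests were adjusted by Benjamini-Hochberg and called at 0.05, and a gene is said to pass by this test unless another tool is named. EdgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives. Both cell types lie in separate tables, so levels were not tested between them. The difference of their Cux1low effects came from a fit of all 12 libraries with an interaction term, added after the data were seen. No 2 libraries of a group agreed within sampling noise, with a chi-square per gene of 8.98 to 86.9, so none were merged.

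Genes named in the text were taken by a fixed rule. Cux1 came first, followed by the 10 largest rises and 10 largest falls among called genes whose libraries both lay beyond both Renilla libraries with a mean of at least 2 CPM, leaving out predicted models. Where fewer than 5 passed, the 5 of smallest p in that direction were named as not passing. Up to 3 called rises and 3 called falls of each gene list and a fixed set of erythroid and stem cell genes were added. A few genes that the rule names are not reported here. Genes outside the rule are said to be chosen after their values were seen.

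A total of 26 gene lists were fixed: adult globins, embryonic globins, haem synthesis, iron, erythroid transcription factors, erythroid membrane, late erythroid clearance, EPO and STAT5, stem and progenitor, megakaryocyte, neutrophil and monocyte, lymphocyte, mast cell and basophil, macrophage, G1/S, G2/M, p53 targets, DNA repair, PI3K and FOXO, interferon, unfolded protein and ATF4, cholesterol synthesis, ribosomal proteins, oxidative phosphorylation, immediate early and sex-linked genes. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation and with fry. No list passed with an estimated correlation or by fry in any comparison. Adult globins, and embryonic globins in MEP, had fewer than 3 testable members.

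Comparisons of Cux1low and Cux1mid share the Renilla libraries, so 100 draws of unchanged groups gave the correlation and covariance that sharing alone produces where groups vary alike. The pipeline was tested on simulated data drawn from the real means, depths and spread, where the share of unchanged genes called was 0.0862% in MEP and 0.102% in RII.

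ATAC-seq peaks were deposited by the authors as 1 list per library of 1 bp summits with a -log10 q value each, in the layout MACS2 writes. An overlap of at least 1 bp between peaks had been planned, which such summits cannot serve. Summits were instead widened to 500 bp and merged, a width listed among the alternatives beforehand, and 1 bp summits are given as a setting. A region was gained when present in both lists of the genotype compared (Cux1low or Cux1mid) and neither Renilla list, and lost in the reverse case. Scores ranked summits within a list for lists of equal length. A common cutoff of -log10 q above 5 and the list medians also set scores of different lists side by side, without adjustment for depth. Depth of these libraries is not given in the sources used here.

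CUX1 peaks were deposited by the authors as 1 list per cell type in the layout of the irreproducible discovery rate (IDR) method, in hg19, with an IDR score of at most 1000, a -log10 global IDR of at least 1.3 and a signal value. The signal of each deposited peak was the sum of the signals in 2 replicate lists (100% of peaks, tolerance 0.001), although 3 CUT&RUN libraries are labelled. These are titled CUX1, CUX2 and CUX3 with no antibody in their labels, so which of them entered, and whether the titles number replicates, is not given in the sources used here. Overlap was tested against 1000 random placements on the same chromosomes. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used for regions and peaks.

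Alternatives covered the pseudocount (0.25 and 4), the filter (none and 5 CPM), scaling (median-of-ratios and quantile), the replicate block, the spread without a trend, only the compared libraries, a log2 fold of at least 1, the tool, leaving out each library in turn, the list tests, the region width and overlap, and lists of equal length. Whether CUX1 binds near changed genes was not analysed, since it needs a human gene annotation of hg19.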

Results

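RNA-seq and ATAC-seq, which marks open chromatin, were collected from 2 mouse cell types: megakaryocyte-erythrocyte progenitors (MEP), the precursors of platelet-forming and red cells, and basophilic erythroblasts of the RII stage, early red cell precursors. Cells came from 3 genotypes named Renilla, Cux1mid and Cux1low, with 2 libraries per genotype, cell type and assay, and Renilla served as the control. The design asked what knockdown of CUX1, a homeodomain transcription factor, changes in these cells. Sites bound by CUX1 were also mapped in human cells, by CUT&RUN in 3 libraries of erythroblasts grown from CD34-positive cells for 7 days and by ChIP-seq in 2 libraries of K562, an erythroleukaemia line. The CUT&RUN libraries are titled CUX1, CUX2 and CUX3 with no antibody in their labels, and whether these titles number replicates is not given in the sources used here. The 29 samples fell into 14 groups. RNA libraries held 18682301 to 24703855 reads assigned to genes in MEP and 9860840 to 12596085 in RII. The labels do not say that the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

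Cux1 itself (mm10 chromosome 5, 136248135 to 136567590) was lower in every library labelled Cux1low than in every Renilla library, and it was not lower in the libraries labelled Cux1mid. In MEP it stood at 72.3 and 65.8 CPM in Renilla, 64.4 and 69.8 CPM in the libraries labelled Cux1mid, and 35.1 and 28.6 CPM in Cux1low. In RII it stood at 56.4 and 46.4 CPM in Renilla, 54.5 and 48.4 CPM in the libraries labelled Cux1mid, and 19.8 and 23.3 CPM in Cux1low. The RII Cux1low mean of 21.5 ± 2.48 CPM against 51.4 ± 7.12 CPM (SD, n = 2) fell by 1.22 on the log2 scale (SE 0.212, limma adjusted p = 0.0125). That call was lost without Renilla 1 (log2 -1.08, adjusted p = 0.196) and without Cux1low 1 (log2 -1.10, adjusted p = 0.056). The MEP mean of 31.9 ± 4.64 CPM against 69.0 ± 4.60 CPM (SD, n = 2) gave a log2 fold of -1.10 (SE 0.139) that did not pass limma (adjusted p = 0.265) or edgeR (adjusted p = 0.298) but passed DESeq2 (adjusted p = 1.29e-06). The fold of the libraries labelled Cux1mid was -0.04 in MEP and 0.01 in RII on the log2 scale, so the Cux1 entry alone does not bear out that label. Another entry that may count a product of this gene, Casp, is given below. Cux2, the close relative of Cux1, had at most 4 reads in any library.

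A separate entry named Casp, which matches no RefSeq symbol, moved where Cux1 did not. CASP is also the name of a Golgi protein made from the Cux1 gene by alternative splicing, and whether this entry counts that transcript is not given in the sources used here. It fell in RII from 59.8 ± 25.3 CPM in Renilla to 7.56 ± 0.503 CPM (SD, n = 2) in the libraries labelled Cux1mid, a log2 change of -2.77 (limma adjusted p = 0.0186, edgeR adjusted p = 0.0174). In MEP it stood at 65.3 and 45.4 CPM in Renilla, 46.8 CPM in library 1 and 6.20 CPM in library 2 of Cux1mid, and 57.3 and 64.6 CPM in Cux1low. In RII Cux1low it stood at 25.8 and 40.6 CPM. The RII call was lost without Renilla 1 (adjusted p = 0.252), without Cux1mid 1 (0.482) and without Cux1mid 2 (0.241).

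**Figure D1:**
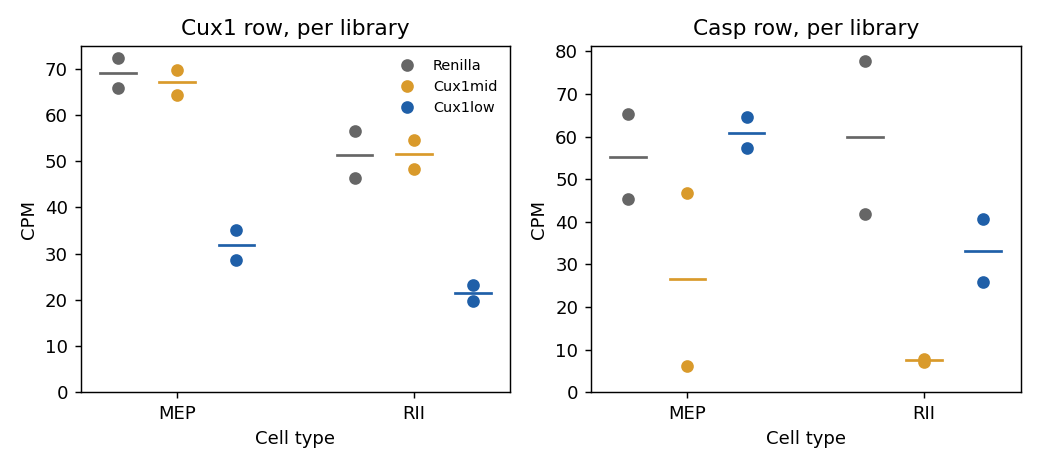
Level in CPM of the Cux1 gene (left) and of the entry named Casp (right) in each RNA library of MEP and RII; points are libraries, lines are group means, and colours are the genotypes in the labels. Cux1 was lower in Cux1low, at 28.6 and 35.1 CPM in MEP and at 19.8 and 23.3 CPM in RII, and Casp was lowest in 3 of the 4 libraries labelled Cux1mid.

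In RII erythroblasts, 2 embryonic globin genes rose in Cux1low. Hba-x, the embryonic alpha-like globin (mm10 chromosome 11, 32276600 to 32278116), rose from 0.469 ± 0.172 CPM in Renilla, which is 6 and 4 reads, to 90.5 ± 12.9 CPM (SD, n = 2), which is 1189 and 1025 reads. Its log2 change was 5.96 on the log2(CPM + 1) scale (limma adjusted p = 2.5e-05). Hbb-bh1, an embryonic beta-like globin, rose from 3.84 ± 0.702 to 24.7 ± 1.22 CPM (SD, n = 2; log2 2.41, adjusted p = 0.00644). Hbb-y, another embryonic beta-like globin named after its values were seen, had 3.41 ± 2.81 CPM against 1.11 ± 0.032 CPM and did not pass (adjusted p = 0.41). The embryonic globin list, with 2 of 5 tested members up and none down, stood higher by camera (adjusted p = 0.0187; adjusted p = 0.905 with an estimated correlation). Without Cux1low 1 or Cux1low 2 the filter dropped Hba-x, so the list test without either (adjusted p = 0.55 and 0.344) no longer covered it. Hbb-bh1 lost its call without Renilla 1 (adjusted p = 0.0601). The adult globin list had too few tested members, and its members are named here after their values were seen. Hbb-b1 stood at 2.26 and 3.73 CPM against 2.95 and 3.56 CPM in Renilla and did not pass (adjusted p = 0.958), Hba-a1, Hbb-bt and Hbb-b2 are listed at 0 in every library, and Hba-a2 and Hbb-bs had at most 1 read. How reads of the adult globin genes were counted or removed is not given in the sources used here. These values therefore do not show whether adult globin was present or changed.

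Genes of terminal red cell maturation fell in RII Cux1low. Of 24 tested genes of the late erythroid clearance list, 7 fell and 1 rose (adjusted over the list alone, 12 fell and 2 rose), and the list stood lower by camera (adjusted p = 6.58e-07; adjusted p = 0.905 with an estimated correlation). Xpo7, a nuclear exportin used in erythroid nuclear condensation, fell from 5609.5 ± 1190 to 2306 ± 457 CPM (SD, n = 2; log2 -1.28, adjusted p = 0.00912). Fam46c fell from 3452.5 ± 15.6 to 1668.5 ± 6.90 CPM (log2 -1.05, adjusted p = 0.00669), and Gabarapl2, an autophagy gene, from 132 ± 9.28 to 63.6 ± 2.79 CPM (log2 -1.04, adjusted p = 0.0115). Nprl3, which lies beside the alpha globin genes and restrains mTORC1, was the member that rose, from 70.3 ± 2.35 to 124.5 ± 26.2 CPM (log2 0.80, adjusted p = 0.0413). Xpo7 and Fam46c lost their calls without Renilla 1 (adjusted p = 0.0956 and 0.06), Gabarapl2 without either Renilla library (0.0825 and 0.0947), and Nprl3 without either Renilla library, either Cux1mid library or Cux1low 1 (adjusted p from 0.0606 to 0.268). EdgeR called none of Xpo7, Fam46c and Nprl3 (adjusted p = 0.114, 0.12 and 0.108).

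Haem synthesis genes moved both ways in RII Cux1low, and few membrane genes passed. Of 19 haem synthesis genes, 4 fell and 2 rose (adjusted over the list alone, 6 and 6), and the list did not pass (camera adjusted p = 0.428). Alas2, the first enzyme of erythroid haem synthesis, fell from 21418 ± 1466 to 9194 ± 12.8 CPM (SD, n = 2; log2 -1.22, adjusted p = 0.0169). EdgeR did not call Alas2 (adjusted p = 0.212), which also lost the call without any 1 of the Renilla or Cux1low libraries (adjusted p from 0.0787 to 0.11). The mitochondrial carrier Slc25a39 fell from 2134 ± 159.7 to 813 ± 124 CPM (log2 -1.40, adjusted p = 0.00644) and the iron-sulphur assembly gene Isca1 from 644 ± 43.9 to 298 ± 13.3 CPM (log2 -1.11, adjusted p = 0.0127). Tmem14c, a porphyrin transporter, and Uros, a haem pathway enzyme, rose by 0.76 and 0.70 on the log2 scale (adjusted p = 0.0472 and 0.0474), and both lost their calls without either Renilla library or Cux1low 1, Tmem14c without Cux1low 2 and Uros without either Cux1mid library (adjusted p from 0.0517 to 0.306). Isca1 also lost its call without Renilla 1 (adjusted p = 0.0669) and without Renilla 2 (0.0711). EdgeR called none of Slc25a39 (adjusted p = 0.058), Isca1 (0.088), Tmem14c (0.211) and Uros (0.242). Of 25 membrane genes, 3 fell, led by Trim10 (log2 -1.22, adjusted p = 0.016), the urea transporter Slc14a1 (log2 -1.08, adjusted p = 0.00371) and the band 3 partner Epb4.2 (log2 -0.87, adjusted p = 0.0133). The membrane list did not pass (camera adjusted p = 0.606; its median log2 fold was 0.105 and its mean -0.0507). Without Renilla 1, Trim10, Slc14a1 and Epb4.2 all lost their calls (adjusted p = 0.125, 0.0601 and 0.188), and Epb4.2 did so without Cux1low 1 as well (0.0581). EdgeR called neither Trim10 nor Epb4.2 (adjusted p = 0.101 and 0.147). The anion exchanger gene Slc4a1 (20604 ± 2281 CPM against 19134 ± 1726 CPM) did not pass.

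Erythroid regulators changed little as a group in RII Cux1low. Of 25 erythroid transcription factors, Ldb1, an adaptor of the GATA1 and TAL1 complex, rose from 114 ± 8.98 to 210.1 ± 20 CPM (SD, n = 2; log2 0.88, adjusted p = 0.0136). Gfi1b, a repressor needed for red cell and platelet lineages, rose from 97.8 ± 1.27 to 171 ± 1.24 CPM (log2 0.80, adjusted p = 0.0464). The list did not pass (camera adjusted p = 0.606). Both genes lost their calls without Renilla 1 (adjusted p = 0.188 for Ldb1 and 0.322 for Gfi1b), without Renilla 2 (0.0591 and 0.192) and without Cux1low 2 (0.0525 and 0.0935), and Gfi1b did so without Cux1low 1 as well (0.144). Gata1 (351 ± 10.6 against 288 ± 12.4 CPM, adjusted p = 0.434), Klf1 (log2 0.04, adjusted p = 0.973), Tal1 (log2 -0.44, adjusted p = 0.242), the fetal globin repressor gene Bcl11a (log2 0.45, adjusted p = 0.327), Gata2 (log2 -0.35), Kit (log2 -0.28) and Myb (log2 -0.42) did not pass. Epor, the erythropoietin receptor gene, stood at 403 ± 27.6 against 271 ± 28.3 CPM and did not pass (adjusted p = 0.0955), and neither did the EPO and STAT5 list (2 up and 1 down of 18, camera adjusted p = 0.306). In the iron list only Slc11a2, an iron transporter, passed among 18 genes, with a rise of 0.78 (adjusted p = 0.0361), lost without either Renilla library or Cux1low 1 (adjusted p from 0.171 to 0.228). The transferrin receptor gene Tfrc had a log2 fold of -0.19 (adjusted p = 0.736), and the list did not pass (camera adjusted p = 0.306). The stem and progenitor gene Mllt3 fell by 0.75 (adjusted p = 0.0472), lost without any 1 of the Renilla or Cux1low libraries (adjusted p from 0.0614 to 0.448), and its list did not pass (0 up and 1 down, camera adjusted p = 0.428). EdgeR called none of Gfi1b, Slc11a2 and Mllt3 (adjusted p = 0.149, 0.16 and 0.114).

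Stress and amino acid response genes rose in RII Cux1low. Of 29 genes of the unfolded protein and ATF4 list, 8 rose and none fell (adjusted over the list alone, 14 and 0), and the list stood higher by camera (adjusted p = 4.62e-07; adjusted p = 0.561 with an estimated correlation). Atf5, a stress-induced transcription factor, rose from 9.04 ± 0.870 to 44.3 ± 12.7 CPM (SD, n = 2; log2 2.15, adjusted p = 0.00371). Trib3 rose from 1.09 ± 0.425 to 5.28 ± 1.29 CPM (log2 1.59, adjusted p = 0.0387) and the asparagine synthetase gene Asns from 107 ± 4.73 to 328 ± 163 CPM (log2 1.52, adjusted p = 0.0203; edgeR adjusted p = 0.054). Without Renilla 1, Renilla 2 or Cux1low 1 the calls of Trib3 (adjusted p from 0.104 to 0.371) and Asns (0.0572 to 0.115) were lost, and Trib3 lost it without Cux1low 2 too (0.0644) and by edgeR (0.0729). The other members that rose were the growth arrest gene Ddit3 (log2 1.08), the tRNA synthetase genes Gars (1.04) and Aars (0.96) and the amino acid transporter genes Slc7a5 (0.89) and Slc3a2 (0.70), named after their values were seen.

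Heat shock chaperones rose in both RII Cux1low libraries, but to very different levels. Hspa1b stood at 254.8 CPM in library 1 and 77.6 CPM in library 2 against 2.14 ± 1.43 CPM in Renilla (SD, n = 2; log2 5.58, adjusted p = 3.99e-04), and Hspa1a at 169 and 34.5 CPM against 1.15 ± 0.885 CPM (log2 5.24, adjusted p = 0.00232). These are near-identical copies, so their counts are uncertain one by one. Hsph1 rose from 61.2 ± 11.8 to 491 ± 433 CPM (log2 2.64, adjusted p = 0.0169; 0.0916 without Renilla 1) and Dnajb1 from 146 ± 11.3 to 307 ± 44.3 CPM (log2 1.06, adjusted p = 0.00874; 0.104 without Renilla 1, 0.0505 without Cux1low 1 and 0.0515 by edgeR). Chaperones made up the 3 members of the immediate early list that rose, among 25, with none down (4 adjusted over the list alone). That list stood higher by camera (adjusted p = 0.00468; adjusted p = 0.905 with an estimated correlation), but its median turned negative without Renilla 2 (log2 -0.156, adjusted p = 0.811) and without Cux1low 1 (-0.00376, 0.978). Levels of this list also differed by replicate number, which unbalances these leave-outs. Its mean log2 level was 5.08 in Renilla 1 and 5.78 in Cux1low 1, and 3.97 in Renilla 2 and 4.71 in Cux1low 2. Egr1, looked at after its values were seen, stood at 49.7, 47.8 and 80.7 CPM in Renilla 1, Cux1mid 1 and Cux1low 1 and at 3.91, 4.56 and 7.86 CPM in the libraries numbered 2. Fos, looked at in the same way, stood at 210, 202 and 210 CPM and at 68.9, 72.5 and 120 CPM.

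Mitotic genes stood higher in RII Cux1low. Of 35 G2/M genes, 2 rose and none fell (adjusted over the list alone, 17 and 1), and the list stood higher by camera (adjusted p = 4.37e-10; adjusted p = 0.905 with an estimated correlation). Prc1, which bundles the central spindle, rose from 438 ± 82.7 to 769 ± 48.3 CPM (SD, n = 2; log2 0.82, adjusted p = 0.0484) and Anln, a cytokinesis scaffold, by a log2 of 0.75 (adjusted p = 0.0457). Both calls were lost without any 1 of the Renilla or Cux1low libraries (adjusted p from 0.0628 to 0.459) and by edgeR (0.189 and 0.202). The G1/S list stood higher with no member called among 35 (camera adjusted p = 8.86e-04, 0.0583 after quantile normalization; adjusted p = 0.905 with an estimated correlation). DNA repair genes did not pass as a list (2 up adjusted over the list alone, camera adjusted p = 0.297), nor did p53 targets (camera adjusted p = 0.817). The p53 gene Trp53 and its target Cdkn1a did not pass.

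Several antiviral genes fell in RII Cux1low. Rsad2, which encodes viperin, fell from 3988 ± 1827 to 649.7 ± 11 CPM (SD, n = 2; log2 -2.54, adjusted p = 0.00118). The exonuclease gene Isg20 fell from 1279 ± 49.6 to 359 ± 6.08 CPM (log2 -1.83, adjusted p = 1.66e-04) and Ifit1 from 56.3 ± 0.269 to 20.7 ± 2.85 CPM (log2 -1.41, adjusted p = 0.0076; 0.0793 without Renilla 1). Stat2, which carries the interferon signal, rose from 64.2 ± 4.85 to 150.4 ± 63.9 CPM (log2 1.15, adjusted p = 0.0418), a call lost without either Renilla library, either Cux1mid library or Cux1low 1 (adjusted p from 0.06 to 0.269) and by edgeR (0.0629). The interferon list, with 4 down and 1 up of 34, did not pass (camera adjusted p = 0.212).

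Among the largest remaining changes in RII Cux1low, Fam213a, a redox protein gene, fell from 843.5 ± 72.7 to 103 ± 38.1 CPM (SD, n = 2; log2 -3.08, adjusted p = 6.92e-05). Lincred1, a long noncoding RNA, fell from 76.7 ± 20.6 to 4.41 ± 0.512 CPM (log2 -3.82, adjusted p = 8.35e-05) and Cdr2 from 2374.5 ± 127 to 462 ± 83.1 CPM (log2 -2.37, adjusted p = 8.35e-05). The peptide transporter gene Slc15a2 fell by 3.55 on the log2 scale, the bone phosphatase gene Phospho1 by 2.64, Igfn1 by 2.75 and Rps3a1 by 2.58. Rps3a1 belongs to a ribosomal protein family with many pseudogenes, so its count is uncertain. Ttc39a fell by 3.08 and its antisense partner Ttc39aos1 by 3.30, and without a stated strand the reads of this pair cannot be told apart. Rises included Dcbld2 (30.9 ± 1.34 against 4.45 ± 1.69 CPM, log2 2.58, adjusted p = 0.00313), C77080 (log2 2.31), the kinase gene Wnk4 (2.27), Sapcd2 (2.26) and the receptor gene Fgfrl1 (2.23). Of the 53 genes named by the rule and called here, 28 were also called by edgeR, 27 with median-of-ratios scaling and 12 without the trend, and 10 were called in every setting tried. Of these 10, the falls were Cdr2, Fam213a, Isg20, Lincred1, Phospho1 and Rps3a1 and the rises Atf5, Dcbld2, Hspa1b and Wnk4. Hba-x was called wherever it was tested, but the filter dropped it when a Cux1low library was left out. Igfn1 was lost without Renilla 1 (adjusted p = 0.121) and Cux1low 1 (0.0564) and by DESeq2 (0.181), Sapcd2 without the same libraries (0.0804 and 0.0524), and C77080 without Renilla 1 (0.0587).

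Markers of other blood cells in RII did not all stay level in Cux1low. The lymphocyte list stood lower with no member called among 24 (camera adjusted p = 2.65e-04; adjusted p = 0.905 with an estimated correlation; 0.656 without Cux1low 2). So did the neutrophil and monocyte list among 29 (adjusted p = 0.0266; adjusted p = 0.905 with an estimated correlation; 0.25 without Renilla 1 and 0.415 without Cux1low 1). S100a8 and S100a9, abundant neutrophil transcripts chosen after their values were seen, stood at 2979 to 4161 CPM and 4312 to 6381 CPM across the RII libraries of every genotype. The mean log2 level of the neutrophil and monocyte list in RII was 7.65 to 8.27, beside 7.26 to 7.44 for erythroid transcription factors. Other erythroid lists stood higher, at 8.235 to 8.826 for late clearance, 8.95 to 9.21 for haem synthesis and 10.01 to 10.34 for membrane genes. RNA of neutrophils or monocytes was thus present in the RII libraries, and changes in RII need not be changes of erythroblasts. Oxidative phosphorylation genes stood slightly lower (0 up and 1 down of 44, camera adjusted p = 0.0468; adjusted p = 0.905 with an estimated correlation), with Cox7b down by 0.78 (adjusted p = 0.048). That list turned positive without Cux1low 1 (median log2 0.187, adjusted p = 0.445) and was lost without Renilla 2 (0.282), Cux1mid 1 (0.0538) or Cux1mid 2 (0.0575). Cox7b was lost without either Renilla library, either Cux1mid library or Cux1low 1 (adjusted p from 0.0742 to 0.31) and by edgeR (0.0658). Of 21 megakaryocyte genes, 2 rose, namely Itga2b, an integrin gene (log2 1.08, adjusted p = 0.0342, lost without either Renilla library or Cux1low 1, adjusted p from 0.137 to 0.296, and by edgeR, 0.0512), and Thbs1, which encodes thrombospondin (log2 1.23, adjusted p = 0.00336). The megakaryocyte list did not pass (camera adjusted p = 0.722). In the macrophage list the lysosomal protease gene Ctsd rose by 0.69 (adjusted p = 0.0333) and Lgmn fell by 1.19 (adjusted p = 0.0408), each lost without either Renilla library (adjusted p from 0.0561 to 0.366) and by edgeR (0.203 and 0.101). Ctsd was also lost without Cux1low 1 (0.186) and Lgmn without Cux1low 2 (0.13) or either Cux1mid library (0.0697 and 0.0671). The macrophage list did not pass (camera adjusted p = 0.648). The mast cell list (camera adjusted p = 0.266), PI3K and FOXO list (0 up and 1 down, Pik3r1, log2 -0.72; camera adjusted p = 0.173), cholesterol synthesis list (0.722), ribosomal protein list (0 up and 1 down; 0.306) and sex-linked list (0.804) did not pass. Pik3r1 was lost without any 1 of the Renilla or Cux1low libraries (adjusted p from 0.0858 to 0.318) and by edgeR (0.127). The genes Spi1, Pik3ip1 and Pf4 did not pass.

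In all, 351 of 11166 genes were called in RII Cux1low against Renilla, 202 up and 149 down (limma, Benjamini-Hochberg), which is 57.5% up. Other scalings turned that balance, with 39.5% up of 152 calls after median-of-ratios factors and 36.8% up of 258 after quantile normalization. The count was 161 by edgeR (43.5% up), 435 by DESeq2 (56.6% up), 133 without the filter (45.9% up) and 24 without the trend (33.3% up). It was 56 without Renilla 1 (39.3% up), 131 without Renilla 2 (45% up) and 123 without Cux1low 1 (31.7% up).

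**Figure D2:**
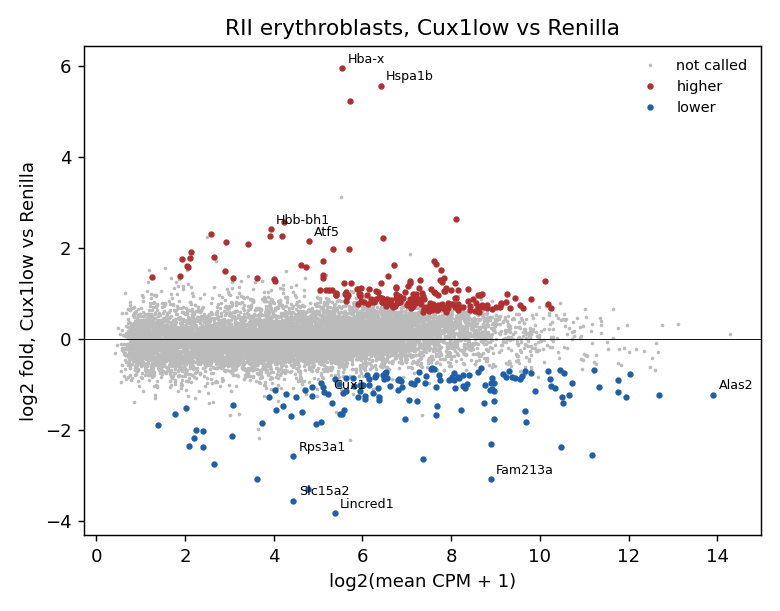
Log2 fold of RII Cux1low against Renilla on the log2(CPM + 1) scale (vertical axis) against log2 of the mean CPM of those 4 libraries plus 1 (horizontal axis), 1 point per tested gene; red points were called higher and blue points lower by limma at adjusted p under 0.05. Hba-x lies at 5.96, Hspa1b at 5.58, Lincred1 at -3.82 and the highly expressed Alas2 at -1.22.

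In MEP, no single gene passed limma or edgeR between Cux1low and Renilla. By camera, ribosomal protein, oxidative phosphorylation, G2/M and erythroid transcription factor genes shifted as groups by small steps. The genes with the smallest p, none of which passed limma, included C77080 (11.3 ± 2.04 against 2.22 ± 0.567 CPM, SD, n = 2; log2 1.94, limma adjusted p = 0.265), the linker histone gene H1f0 (20.6 ± 1.74 against 48.6 ± 7.19 CPM; -1.19, 0.265) and the phosphatase gene Ptpn14 (15.1 ± 2.47 against 43.2 ± 8.19 CPM; -1.45, 0.265). They were followed by Npm3 (45.4 ± 4.49 against 85.6 ± 0.863 CPM; -0.90, 0.307) and the mitotic phosphatase gene Cdc25b (57.7 ± 4.61 against 25.7 ± 5.86 CPM; 1.15, 0.43). Ccnb1ip1 had 1 and 0 reads in Cux1low against 61.8 and 17.9 CPM in Renilla, and did not pass limma either (adjusted p = 0.265). Ccdc117 (log2 0.59) and Frmd4a (0.73) also had small p without passing limma. DESeq2 called each of these 8 genes (adjusted p from 1.86e-08 to 0.00483). Kit, the stem cell factor receptor gene, had a log2 fold of -0.39 (adjusted p = 0.814). Ribosomal protein genes, 70 of 76 with a negative fold, and oxidative phosphorylation genes, 45 of 45, stood lower by camera (adjusted p = 1.01e-05 for both; adjusted p = 0.949 with an estimated correlation). Cell cycle G2/M genes stood higher (30 of 35 positive, adjusted p = 0.00388) and erythroid transcription factors lower (19 of 25 negative, adjusted p = 0.0265), both with adjusted p = 0.949 with an estimated correlation. Without Cux1low 1 the ribosomal and oxidative phosphorylation calls were lost (adjusted p = 0.0771 and 0.205), and without Cux1low 2 those of G2/M and the transcription factors (0.052 and 0.509). Leaving out Renilla 1 ended the transcription factor call (0.108), and leaving out Renilla 2 ended the G2/M call (0.112).

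Limma called 0 of 10746 MEP genes in Cux1low against Renilla and edgeR 0, with 578 at an unadjusted p under 0.05, while DESeq2 called 60, of which 18 rose and 42 fell; limma called 1 gene without Renilla 2. The unadjusted count was 1472 without Cux1mid 1, 1464 without Cux1mid 2 and 1469 with only the 4 libraries compared. It was 199 without Renilla 1, 222 without Renilla 2 and 261 without Cux1low 2. On simulated data of the same size, limma called 61.2% of genes changed 2-fold and 86% of those changed 4-fold in MEP, and 36.7% and 90% in RII. Simulated genes varied independently, and no simulated library was made to stand apart as MEP Cux1mid 1 does. These shares may therefore not hold for the real libraries.

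In MEP, the library labelled Cux1mid 1 stood apart from the other 5. It lay at 41.2 on the first principal component, which held 53.6% of the variance, while the others lay between -16.6 and -2.79. Looked at after their values were seen, the proliferation gene Mki67 stood at 771 CPM there against 2004 to 2570 CPM elsewhere, and the ribosomal RNA entry Rn45s at 5464 CPM against 1193 to 2092 CPM. Spi1, a myeloid and lymphoid transcription factor gene, stood at 12.7 CPM against 3.05 to 5.29 CPM, and Pik3ip1, an inhibitor of PI3K, at 29.0 CPM against 4.83 to 11.1 CPM. Its Casp level of 46.8 CPM lay near Renilla, where the other 3 libraries labelled Cux1mid had 6.20 to 7.91 CPM. Whether its label is right is not settled by these values, and every MEP comparison of the libraries labelled Cux1mid rests on it.

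Against Renilla, no gene passed limma or edgeR in the MEP libraries labelled Cux1mid. The smallest p belonged to Frmd4a (159 ± 10.2 against 62.0 ± 3.50 CPM, SD, n = 2; log2 1.34, limma adjusted p = 0.128), the circadian gene Per1 (203 ± 36.1 against 37.2 ± 11.5 CPM; 2.44, 0.938), the glucocorticoid-induced gene Tsc22d3 (64.8 ± 22.0 against 21.9 ± 1.96 CPM; 1.48, 0.987), Cttnbp2 and Trnp1. Among lower genes it belonged to Naip2 (9.77 ± 0.00647 against 18.5 ± 1.37 CPM; -0.85, 0.987), Dgke, Ifit2, Rhobtb3 and Zfand4. DESeq2 called Frmd4a (adjusted p = 3.42e-11), Per1 (3.94e-09), Tsc22d3 (3.35e-04), Naip2 (0.0138) and Trnp1 (0.0308). Lymphocyte genes stood higher (12 of 12 positive, camera adjusted p = 2.68e-04; adjusted p = 0.991 with an estimated correlation), with a mean log2 level of 3.38 in library 1 of Cux1mid against 1.79 to 2.74 elsewhere, and the call was lost without that library (adjusted p = 0.446). G2/M genes stood lower (adjusted p = 1.72e-04; adjusted p = 0.547 with an estimated correlation; 0.111 without Cux1mid 1). Cholesterol synthesis genes stood lower (0.00223) and PI3K and FOXO genes higher (0.0475), each with adjusted p = 0.991 with an estimated correlation. Without Cux1mid 2 the cholesterol median was 0.0212 (adjusted p = 0.625). The PI3K and FOXO call was lost without Renilla 2 (0.161), Cux1mid 2 (0.218), Cux1low 1 (0.0507) or Cux1low 2 (0.0605). Limma and edgeR called 0 genes, with 258 at an unadjusted p under 0.05, and DESeq2 called 5. Limma called 1115 genes, 359 up and 756 down, without Cux1mid 2, when Cux1mid 1 stood alone for its group, and 2 without Cux1mid 1. The unadjusted count was 56 without Renilla 1, 146 without Renilla 2, 547 without Cux1mid 1, 3106 without Cux1mid 2, 489 without a filter and 172 with only the 4 libraries compared.

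In RII, a pair of genes passed limma between the libraries labelled Cux1mid and Renilla. Thbs1, which encodes thrombospondin, rose from 49.7 ± 2.23 to 144.8 ± 13.7 CPM (SD, n = 2; log2 1.52, limma adjusted p = 0.0143), and Casp fell. Without Renilla 1, Cux1mid 1 or Cux1mid 2 the Thbs1 call was lost (adjusted p = 0.252, 0.475 and 0.0833). Not past limma were the next smallest p: the interferon-induced GTPase gene Irgm2 (414 ± 19.6 against 193 ± 11 CPM; log2 1.10, 0.739) and the aminopeptidase gene Enpep (16.2 ± 9.11 against 2.51 ± 0.354 CPM; 2.19, 0.575), with Igtp, Clec4e and Lifr. Lower levels that did not pass limma were those of Cd14, a lipopolysaccharide receptor gene (4.21 ± 2.08 against 21.9 ± 9.06 CPM; -2.13, 0.406), Gclm, Pnp, Rnf114 and Shmt2. DESeq2 called Irgm2 (adjusted p = 0.0168), Enpep (4.5e-04) and Cd14 (5.12e-07). Limma called 2 genes and edgeR 2, DESeq2 5 and limma after quantile normalization 1; limma called 0 without Renilla 1, without Cux1mid 1, without Cux1mid 2, without the filter or without the trend.

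Several groups shifted in RII libraries labelled Cux1mid, mostly through library 1. G1/S genes (camera adjusted p = 6.2e-10), G2/M genes (2.74e-09), membrane genes (5e-07), haem synthesis genes (1.38e-05), cholesterol synthesis genes (0.00584), DNA repair genes (0.0384) and erythroid transcription factors (0.0433) stood lower. Mast cell and basophil genes (4.39e-04), stem and progenitor genes (0.0178) and megakaryocyte genes (0.0433) stood higher. With an estimated correlation the adjusted p was 0.855 for cholesterol synthesis, 0.929 for DNA repair and 0.765 for the other 8 lists. Among mast cell genes, picked after their values were seen, the protease gene Mcpt8 stood at 40.5 ± 39.3 against 18.1 ± 0.962 CPM and Prss34 at 115 ± 112.3 against 51.8 ± 3.24 CPM (SD, n = 2), and neither passed. Without Cux1mid 1, 9 of these 10 calls were lost or turned. The adjusted p became 0.673 for G1/S, 0.806 for membrane, 0.673 for haem, 0.0624 for DNA repair, 0.298 for transcription factors, 0.839 for mast cell, 0.89 for stem and progenitor and 0.0613 for megakaryocyte genes, while G2/M genes then stood higher (0.00514). The cholesterol call was lost without Cux1mid 2 (0.773) or Renilla 2 (0.355). Quantile normalization ended the calls of erythroid transcription factors (0.365), DNA repair (0.0662) and megakaryocyte genes (0.0747). Without Renilla 1 the calls of membrane genes (0.854), mast cell genes (0.265), stem and progenitor genes (0.106) and transcription factors (0.474) were lost, without Renilla 2 that of DNA repair (0.854), and the megakaryocyte call without Renilla 2 (0.174), Cux1mid 2 (0.204), Cux1low 1 (0.134) or Cux1low 2 (0.0615).

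Compared directly, RII Cux1low libraries differed from those labelled Cux1mid in the embryonic globin, mitotic and late erythroid lists by camera. The chaperone genes Hspa1a and Hspa1b, which have no list of their own, also differed. Hba-x (90.5 against 0.448 CPM, log2 6.0, limma adjusted p = 1.89e-05), Hspa1b (4.94), Hspa1a (4.85), Dcbld2 (3.12) and Cd14 (3.05, adjusted p = 0.00148) rose. Slc15a2 (-4.07), Lincred1 (-3.99), Enpep (-3.42), Rps3a1 and Ttc39aos1 (both -2.94) fell, as did Cux1 (-1.22, adjusted p = 0.00982; log2 -1.14 and adjusted p = 0.102 without Cux1mid 1). G2/M genes stood higher with 14 of 35 up (camera adjusted p = 7.57e-16), G1/S genes with 2 up (4.93e-09), unfolded protein and ATF4 genes with 10 of 29 up (1.01e-05) and immediate early genes with 4 up (0.00281). Late erythroid clearance genes stood lower with 7 down and 2 up (4e-05). Lymphocyte (0.00173), neutrophil and monocyte (0.00432), mast cell (0.00571), stem (0.0491) and PI3K and FOXO genes (0.0491) also stood lower, and DNA repair genes and embryonic globins higher (0.0491 for both). With an estimated correlation none of the 12 passed (adjusted p from 0.626 to 0.893). Only the G2/M, G1/S and ATF4 tests held in every library left out. Late clearance was lost without Cux1low 2 (0.0758), lymphocyte without Cux1low 2 (0.59), neutrophil without Cux1mid 1 (0.199) or Cux1low 1 (0.0933), mast cell without Cux1mid 1 (0.1), immediate early without Cux1mid 2 (0.217) or Cux1low 1 (0.782). The 4 lists at 0.0491 were lost without Cux1mid 1 (0.199, 0.445, 0.84 and 0.0514 for globins, stem, repair and PI3K) or Cux1low 2 (0.516, 0.259, 0.219 and 0.249) and with a pseudocount of 0.25 (0.0614, 0.0567, 0.0526 and 0.0566). The globin list was also lost without Cux1low 1 (0.782), and without either Cux1low library it no longer held Hba-x, which the filter dropped. The PI3K and FOXO call was also lost without Cux1mid 2 (0.0565), and quantile normalization ended those of globins (0.0864), stem (0.0864) and repair genes (0.157).

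Limma called 529 genes between RII Cux1low and the libraries labelled Cux1mid, 363 up and 166 down, or 68.6% up, against 58.3% up of 252 after median-of-ratios scaling and 51.2% up of 391 after quantile normalization. The count was 270 by edgeR (63% up), 667 by DESeq2 (68.4% up) and 240 without the filter (58.3% up). The balance turned without the trend (39% up of 59), without Cux1mid 1 (32.4% up of 102) and without Cux1low 1 (43.7% up of 190). In MEP limma and edgeR called 0, with 794 at an unadjusted p under 0.05, and DESeq2 89, 21 up and 68 down; limma called 1866, 1075 up and 791 down, without Cux1mid 2. The unadjusted count was then 3749, against 302 without Cux1low 2, 470 without Renilla 1, 468 without Renilla 2 and 467 with only the 4 libraries compared. Among MEP genes the smallest p belonged to genes that included Naip2, C77080, Dcbld2 and Ugt8a, higher in Cux1low, and Ccnb1ip1, Npm3, Ptpn14, H1f0 and Cux1, lower. None of these passed limma or edgeR, and DESeq2 called each (adjusted p from 6.36e-09 to 0.00139). MEP G2/M genes stood higher in Cux1low than in the libraries labelled Cux1mid (camera adjusted p = 5.86e-09; adjusted p = 0.212 with an estimated correlation). Oxidative phosphorylation (3.86e-05), ribosomal protein (4.06e-05), transcription factor (0.0126), interferon (0.0126), stem (0.0164) and lymphocyte genes (0.0279) stood lower (adjusted p = 0.944 with an estimated correlation), and without Cux1mid 1 all 6 were lost (0.333, 0.13, 0.0737, 0.762, 0.13 and 0.762).

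The changes of Cux1low and of the libraries labelled Cux1mid against Renilla shared little in RII. The correlation of their log2 folds across genes was 0.0871, where unchanged groups simulated against the same Renilla libraries gave 0.501 on average, and the covariance was 0.00836 against a simulated 0.0441, a difference of -0.0358. With 1 Renilla library for each, the correlation was -0.167 or -0.186. Thbs1 was the 1 gene called up in both, where independent lists would share 0.0181 genes and the simulated groups shared 0.15 on average and up to 2. No gene was called down in both (simulated 0.07 on average). In MEP the correlation was 0.28 against a simulated 0.5 and the covariance 0.0193 against 0.0332, a difference of -0.0139. The split Renilla libraries gave 0.105 or -0.00394 in MEP. A simulated correlation near 0.5 is what groups of equal spread give, and the real groups differed in spread. Between the libraries of a group the chi-square per gene was 8.98 in MEP Renilla, 86.9 in Cux1mid and 17.75 in Cux1low. In RII it was 17.99, 24.12 and 30.55 in the same order. The gap to the simulated values therefore need not come from genotype. Genes are not independent replicates, and these correlations describe the libraries.

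Genes of smallest p in Cux1low overlapped between MEP and RII, each measured against its own Renilla libraries. The log2 folds correlated at 0.397 across 10232 genes, and of the 200 genes with the smallest p in each direction, 26 were shared among rises and 27 among falls where 3.91 would be shared by chance (one-sided Fisher exact p = 1.17e-14 and 1.32e-15). C77080, Wnk4 and Dcbld2 were among those higher in both. Ptpn14 (log2 -1.45 in MEP and -1.99 in RII), H1f0 (-1.19 and -1.46), Ehd3 (-2.00 and -1.15), Rsad2 and Rps3a1 were among those lower in both, named after their values were seen. For the libraries labelled Cux1mid the correlation was 0.248, with 24 rises and 13 falls shared (Fisher exact p = 7.9e-13 and 1.48e-04). At the adjusted threshold the overlap was 0 in both comparisons, since limma called 0 genes in MEP. Neighbouring genes and genes of 1 pathway are not independent, so these p-values are too small. The labels also do not say whether MEP and RII libraries came from the same animals. If they did, the comparisons in both cell types would not be independent.

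More ATAC summits were listed in RII Cux1low than in Renilla, at 12307 and 13592 in Cux1low, 9713 and 8023 in Renilla and 8899 and 7761 in the libraries labelled Cux1mid. Read depth, which is not given, was not accounted for. Summits widened to 500 bp and merged gave 16559 regions, of which 1737 were present in both Cux1low lists and neither Renilla list and 47 the reverse, where the highest of the other ways to pair the 4 libraries gave 237 in a direction. The highest-scoring summits alone, with lists of equal length, gave 368 gained and 214 lost regions, against 132 in the other pairings. The lists of Cux1low also had higher scores, with a median -log10 q of 17.8 and 26.4 against 9.93 and 8.43 in Renilla. There are 3 ways to split 4 libraries into pairs, so no exact p can fall below 0.333. Regions gained and lost moved by over 1.5 times in most leave-outs, with gained regions at 3375 without Renilla 1, 4332 without Cux1low 1 and 3280 without Cux1low 2, and lost regions at 541 without Renilla 1, 876 without Renilla 2, 93 without Cux1low 1 and 112 without Cux1low 2.

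Regions gained in RII Cux1low lay near several named genes (mm10). A gained region on chromosome 11 at 32264968 to 32265553 lay within Nprl3 and 11047 bp from Hba-x. On chromosome X, gained regions overlapped an end of Alas2 (150547048 to 150547555) and lay within Gata1 (7967725 to 7968425 and 7971220 to 7971727). Others lay within Gfi1b (chromosome 2, 28616848 to 28617350) and C77080 (chromosome 4, 129238987 to 129239569). Further regions overlapped an end of Hspa1b (chromosome 17, 34959191 to 34959694) and lay 442 bp from Klf1 (chromosome 8, 84901039 to 84901540). Of genes called up, 34.7% (70 of 202) had a gained region within 50 kb, against 40.5% (60 of 148) of genes called down and 29.3% (3155 of 10758) of genes not called. Genes called down had one more often than genes not called (odds ratio 1.64, two-sided Fisher exact test, adjusted p = 0.0109 over 9 tests), and genes called up did not pass (1.28, adjusted p = 0.184). Regions present in all 4 lists also lay more often near called genes (96% up, 91.2% down, 79.6% not called).

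**Figure D3:**
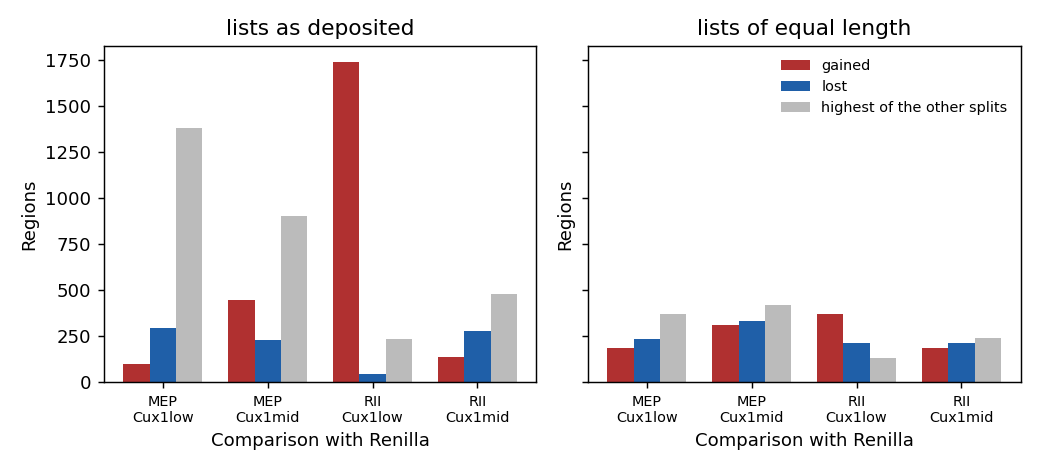
Number of 500 bp ATAC regions present in both libraries labelled Cux1low or Cux1mid and neither Renilla library (gained) or the reverse (lost) for each cell type and genotype, and the highest count of the other ways to pair the same 4 libraries (grey). Lists are as deposited (left) or of equal length by score (right, same scale). With lists as deposited RII Cux1low had 1737 gained and 47 lost regions, and with lists of equal length 368 and 214.

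In MEP and in the libraries labelled Cux1mid, ATAC regions separated the genotypes no better than other pairings did. MEP Cux1low had 100 gained and 296 lost regions of 17333, where the highest other pairing gave 1380, and its library 1 listed 4707 summits against 13876 in library 2. MEP libraries labelled Cux1mid had 449 gained and 232 lost of 17957 against 901, and RII libraries labelled Cux1mid 139 gained and 281 lost of 12423 against 480. Lost regions included 1 near Bcl11a in MEP Cux1low (chromosome 11, 24076015 to 24076791) and 1 at Gata1 in MEP Cux1mid (chromosome X, 7971075 to 7971741). For each pair of lists, the share of the shorter list's summits with a summit of the other within 250 bp was taken. In MEP this share was 64.2 to 75.4% within a genotype and 65.6 to 75.5% between genotypes. In RII it was 77.0 to 82.1% within and 72.9 to 86.4% between. It can rise with the length of the longer list, which was not adjusted for. Leaving out a library raised the numbers of gained and lost regions, since fewer lists must then agree, to 231 to 3616 gained and 344 to 3839 lost in MEP Cux1low.

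CUX1 peaks in human erythroblasts overlapped those in K562 far more than peaks placed at random along the chromosomes. Random placement was not limited to open chromatin or promoters, so the excess does not tell shared CUX1 binding from shared open chromatin. Of 4716 peaks in CD34-derived erythroblasts at day 7, 1711 overlapped 1 of 26497 K562 peaks (hg19), or 36.3% (Wilson interval 34.9 to 37.7), against 1.87% on average over 1000 random placements on the same chromosomes, a 19.4-fold excess (one-sided permutation p = 0.001, the smallest that 1000 draws can give). With peaks moved by 50 kb to 1 Mb instead, the random share was 2.87% and the excess 12.7-fold. From the K562 side, 1822 peaks or 6.88% overlapped. The share changed little with the authors' signal, with 37.1% among the 1179 CD34 peaks of highest signal and 35.7% among the 1179 of lowest. The first peak of the deposited K562 list (signal 191.3) lay at chromosome 17, 43422135 to 43423819. That of the CD34 erythroblast list (signal 32.54) lay at chromosome 16, 47538681 to 47539269. Neither of these overlapped the other list. The assays differ and each list was already combined from replicates, so the overlap has no replicate spread.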

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

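The fit of both cell types with an interaction term and the handling test were chosen after the results were seen, while the prediction on cell maturity was written before its result.

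Effects of Cux1low against Renilla differed between the cell types for 11 of 11702 genes, 1 with a higher and 10 with a lower effect in RII (limma interaction, Benjamini-Hochberg). Among genes named in the report, Hba-x had an RII effect above the MEP effect by a log2 of 5.33 (SE 0.363, adjusted p = 9.58e-05), with 17 and 13 reads in MEP Cux1low against 5 and 0 in MEP Renilla. The RII effect was lower for Lincred1 by a log2 difference of -3.34 (SE 0.419, adjusted p = 0.01), for Fam213a by -2.93 (SE 0.287, adjusted p = 0.00237), for Cdr2 by -2.02 (SE 0.251, adjusted p = 0.01) and for Isg20 by -1.72 (SE 0.241, adjusted p = 0.0212). Hbb-bh1 (difference 2.44, adjusted p = 0.0531) and Cux1 (-0.12, adjusted p = 1) did not pass. For the libraries labelled Cux1mid, limma called 0 interactions.

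The RII Cux1low pattern, with the late clearance list lower and the embryonic globin, ATF4 and G2/M lists higher by camera (adjusted p from 0.561 to 0.905 with an estimated correlation), may reflect a less mature mix of cells or handling rather than an effect within each cell. The 2 gene sets used to mark maturity were chosen by levels in the libraries labelled Cux1mid, which this contrast does not use. The MEP levels thus rest in part on Cux1mid 1, which stood apart from the other MEP libraries. Genes at least 4-fold higher in MEP than in RII had a median log2 fold of -0.0315, at -0.329 in library 1 and 0.29 in library 2, where a less mature mix needs both above 0 (-0.0753 and 0.0373 against the Renilla library of the same number). Genes at least 4-fold higher in RII had a median of -0.196, below 0 in both libraries. This set includes the neutrophil gene S100a8, at 6.96 and 1.46 CPM in MEP and 4125 and 3601 CPM in RII libraries labelled Cux1mid. A lower median of this set need not mark red cell maturity, so maturity remains open. Immediate early genes without their chaperones had a median of 0.34, at 0.782 in library 1 and -0.0395 in library 2 against both Renilla libraries, and at 0.205 and 0.439 against the Renilla library of the same number, so handling cannot be told apart from genotype with 2 libraries. An effect of lower Cux1 within the cells also remains open and was not tested apart from these. The ribosomal RNA entry Rn45s also stood lower in RII Cux1low (2145 and 2573 CPM) than in Renilla (5741 and 3539 CPM). What this reflects was not tested.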

How the results depend on the processing

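Windows of 1 kb, summits with a -log10 q above 5 and the interaction fit were chosen after the data were seen; all other settings were planned. Values behind a library left out assume that a lone library varies like the other groups. The cause of the differences was not tested, except that asking for a log2 fold of at least 1 can only lower a count of calls. Across settings, named genes kept their side of the threshold in 2537 comparisons, lost the call in 264 and gained it in 55. In 0 comparisons the direction turned where either setting passed. For gene lists the numbers were 1332, 163, 92 and 30. Turns of direction where neither setting passed are counted among those kept. With 2 libraries per group and 9860840 to 24703855 reads, changes of 1.5-fold were called for 2% of simulated genes in MEP and 8.16% in RII. Shares in the real libraries may differ, since simulated genes varied independently.

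Counts of changed genes moved as follows. In RII Cux1low against Renilla (351), the count was 133 without a filter, 152 with median-of-ratios scaling, 24 without a trend, 161 by edgeR and 165 at a log2 fold of at least 1. Leaving out a library gave 56 to 311 (without Renilla 1, lowest; without Cux1mid 2, highest). In RII Cux1low against Cux1mid (529), these were 240, 252, 59, 270 and 192, and 102 (without Cux1mid 1) to 453 with a library left out. In RII Cux1mid against Renilla (2), the count was 0 without a filter or a trend, 1 with quantile normalization, 5 by DESeq2 and 0 to 3 with a library left out (0 without Renilla 1 or either Cux1mid library). In MEP (0 in each), DESeq2 called 60 for Cux1low, 5 for Cux1mid and 89 for Cux1low against Cux1mid. In that last comparison a pseudocount of 0.25 and only the 4 libraries compared each gave 1. Leaving out a library gave 0 to 1 in MEP for Cux1low (1 without Renilla 2), 0 to 1115 for Cux1mid and 0 to 1866 between both, each highest without Cux1mid 2.

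The replicate numbers were not taken to pair the libraries, since the labels do not say so and not every correlation was over 0.1: deviations of same-numbered libraries correlated at -0.206 (Renilla and Cux1mid), 0.0626 (Renilla and Cux1low) and 0.277 (Cux1mid and Cux1low) in MEP, and at 0.0854, 0.317 and 0.215 in RII, where Egr1 differed by number in each genotype. The fit with the replicate block called 423 genes in RII Cux1low against Renilla, of which 348 were shared with the fit without it, 2 in RII Cux1mid against Renilla, 620 between both and 0 in MEP. With the block 7 lists passed in MEP Cux1mid instead of 4, and it changed no other count of calls by over 1.5 times.

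No list passed camera with an estimated correlation or fry, with 0 of 4 in MEP Cux1low, 0 of 4 in MEP Cux1mid, 0 of 7 between both, 0 of 9 in RII Cux1low, 0 of 10 in RII Cux1mid and 0 of 12 between both. Leaving out a library gave 3 to 10 lists in MEP Cux1mid (10 without Renilla 2 or Cux1mid 2, 9 without Cux1mid 1) and 5 to 11 between both in MEP (11 without Cux1mid 2).

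The direction of a list test turned in 30 comparisons where either setting passed, each with a library left out. Turns where neither setting passed were not counted. Their median log2 folds ranged as follows, with the library whose loss turned the test in brackets. In MEP Cux1low megakaryocyte genes ranged from -0.235 to 0.429 (Renilla 2). In MEP Cux1mid the ranges were -0.165 to 0.53 for megakaryocyte genes (Renilla 1), -0.306 to 0.0212 for cholesterol synthesis (Cux1mid 2) and, all turned by Cux1mid 1, -0.698 to 1.39 for neutrophil, -0.147 to 0.458 for interferon, -0.0887 to 0.207 for ribosomal and -0.0917 to 0.22 for oxidative phosphorylation genes. Between both in MEP they were -1.12 to 0.587 for neutrophil and -0.586 to 0.0941 for interferon genes (Cux1mid 1). In RII Cux1low they were -0.372 to 0.724 for macrophage and -0.353 to 0.187 for oxidative phosphorylation genes (Cux1low 1) and -0.156 to 0.933 for immediate early genes (Renilla 2 and Cux1low 1).

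In RII Cux1mid, leaving out Cux1mid 1 turned haem synthesis (-0.282 to -0.0864), transcription factor (-0.103 to 0.00555), stem (-0.0689 to 0.511), neutrophil (-0.149 to 0.278), macrophage (-0.305 to 0.756), G1/S (-0.318 to -0.0119) and G2/M genes (-0.356 to 0.0532). It also turned DNA repair (-0.183 to 0.0792), ribosomal (-0.151 to 0.2) and oxidative phosphorylation genes (-0.139 to 0.106). Late clearance genes (-0.131 to 0.12) turned without Renilla 1 or Cux1mid 1, interferon genes (-0.17 to 0.277) without Cux1mid 2 and immediate early genes (-0.448 to 0.511) without Renilla 1. Between both in RII, macrophage genes (-0.594 to 0.552) turned without Cux1mid 1 or Cux1low 2 and ribosomal genes (-0.399 to 0.266) without Cux1low 1. The test's direction is camera's, which can differ in sign from the median.

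Overlaps by the top 200 genes in each direction were 53 for Cux1low between MEP and RII and 37 for Cux1mid (0 by adjusted p), and 53 in MEP and 15 in RII between Cux1low and Cux1mid. Correlations of their folds turned from 0.28 to -0.00394 in MEP and from 0.0871 to -0.167 and -0.186 in RII with 1 Renilla library for each.

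Counts of ATAC regions rest on width, list length and library. With 1 bp summits, gained and lost regions were 53 and 99 in MEP Cux1low (100 and 296), 108 and 93 in MEP Cux1mid (449 and 232), 651 and 120 in RII Cux1low (1737 and 47), and 151 lost in RII Cux1mid (281). Lists of equal length gave 188 gained in MEP Cux1low and 368 gained and 214 lost in RII Cux1low. Summits with a -log10 q above 5 gave 22 gained and 175 lost in MEP Cux1low, 287 gained in MEP Cux1mid and 18 lost in RII Cux1low. Lost regions in RII Cux1low were 98 when windows had to share 50% of the shorter and 20 with windows of 1 kb. Leaving out a library raises counts by construction, since fewer lists must agree. Gained and lost regions then ranged from 231 to 3616 and 344 to 3839 in MEP Cux1low, 928 to 3858 and 383 to 1564 in MEP Cux1mid, 2212 to 4332 and 93 to 876 in RII Cux1low, and 297 to 1206 and 513 to 1880 in RII Cux1mid.

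The overlap of CUX1 peaks held under every setting, at 27.35 to 36.28% of CD34 peaks, each above its random placements, with an excess of 12.7-fold for moved peaks, 24.9-fold at 50% overlap and 27.2-fold for peaks of higher signal. The planned tests of CUX1 binding near changed genes (promoter or 50 kb, either peak list, matched background) were not run for want of an hg19 annotation.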

Other observations

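The tests of list length and of genes near gained regions were chosen after the results were seen, while the prediction on strain segments was written before its result.

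Among genes ranked within the 200 smallest p in both cell types for Cux1low, those higher in both included Foxm1, which drives mitotic gene expression, Mybl1 and the spindle gene Prc1. These were picked after their values were seen, and none passed limma in MEP. Ccnb1ip1, a gene of meiotic crossover, was listed at 0 in both RII Cux1low libraries against a mean of 1.64 CPM in RII Renilla, and at 1 and 0 reads in MEP Cux1low. In MEP Ccnb1ip1 stood at 61.8 and 17.9 CPM in Renilla and at 39.1 and 62.1 CPM in the libraries labelled Cux1mid.

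In MEP, the circadian gene Per1 stood at 45.3 and 29.1 CPM in Renilla, 229 and 177 CPM in the libraries labelled Cux1mid and 85.3 and 159 CPM in Cux1low. In the library labelled Cux1mid 1 of MEP, Casp was at 46.8 CPM, within the range of Renilla, where the other 3 libraries labelled Cux1mid had 6.20 to 7.91 CPM. Neutrophil genes had a mean log2 level of 3.59 in that MEP library against 1.80 to 2.86 in the others. In RII, the ribosomal RNA entry Rn45s, looked at after its values were seen, stood at 5741 and 3539 CPM in Renilla, 3611 and 4304 CPM in the libraries labelled Cux1mid and 2145 and 2573 CPM in Cux1low.

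Genes ranked alike in MEP and RII Cux1low may mark chromosome segments of another mouse strain carried along with the genotype. Of 52 such genes with a position, 10 had another of the set 50 kb to 2 Mb away, where 10000 random gene sets gave 7.12 on average and up to 21 (one-sided permutation p = 0.243). The number lay above the random mean without passing, so segments remain open. A shared response of both cell types to lower Cux1 was not tested apart from this.

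The excess of gained ATAC regions in RII Cux1low may come from deeper or cleaner libraries that list more summits. Of 1737 gained regions, 14.6% (254) had a summit within the highest-scoring 8023 of both Cux1low lists, between the under 10% and over 50% that would have decided, so list length and chromatin cannot be told apart without read depth. If gained regions marked genes that rose, they would lie nearer to those than to genes that fell. The odds ratio of a region within 50 kb was 0.778, genes up against genes down (two-sided Fisher exact p = 0.265, adjusted p = 0.398), which decides neither way. For the split itself, RII Cux1low gave 1737 regions where the highest of the other splits gave 237, and 3 splits are too few for a share under 0.05.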
